A study of Rattus norvegicus with 6 samples.

How the data were processed

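The series holds 6 mRNA sequencing libraries from rat mandibular condylar chondrocytes, 3 of 2D culture and 3 of condylar cartilage organoids. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an mRNA kit for the DNBSEQ platform. The submitters' processing notes name HISAT, HISAT2, Bowtie2, RSEM and DESeq2 without versions or roles. The genome build, the annotation and the strand setting are not given in the sources used here, so no coordinates are reported.

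The authors deposited a table of expected counts (estimated counts that need not be whole) per gene for each library, with 17954 genes identified by gene ID and symbol, and 0 rows that name no gene. The values are not normalised. Between 1846 and 2501 values per library are not whole, which happens where reads are shared among genes, and such genes are given as uncertain where named (12 of the named genes have a fractional value in at least 1 library). Estimated counts were rounded to whole numbers before testing. Gene names are those of the files. A RefSeq gene table of assembly GRCr8 served only to match names, and held 17720 of the 17954 IDs. A share of mitochondrially encoded transcripts was planned and not analysed here.

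Library totals were 18592574 to 26472447 counts, so that 3 counts, the limit that a count of 0 allows, correspond to 0.0917 to 0.18 CPM in a library after scaling. Intervals and limits cover counting error only. A fold against a group with 0 counts was set against 3 counts over the group and is written as "at least". With 1 to 3 counts in the lower group the ratio of pooled levels is given with a 95% exact interval.

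Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10), libraries were scaled by TMM (factors 1.233, 1.266 and 1.231 for 2D culture, 0.662, 0.896 and 0.877 for organoids), and groups were compared by the robust quasi-likelihood F-test with Benjamini-Hochberg adjustment at 0.05. The standard error is the absolute log2 fold change over the square root of F. Replicate numbers were not used as a block. A total of 34 gene lists with 784 entries was fixed before the data were examined, and 771 entries matched a gene in the files. Lists with at least 3 tested members (32 lists) were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and beside it with an estimated correlation and with fry, which tests whether the members move one way and does not compare them with other genes. Shares of counts were compared with two-sided exact permutation tests over 5 measures. Replicates were compared pairwise before averaging, and no pair agreed within sampling noise (chi-square per degree of freedom from 8.8 up).

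The genes named in the text follow a rule fixed before the data were examined: 12 panel genes, the 8 largest rises and the 8 largest falls among called genes with at least 10 CPM in the higher group and no overlap between groups, and for each list up to 3 called members of at least 1 CPM with the largest change plus the largest in the opposite direction. It gave 115 genes, 111 of them called, of which the text names a part. Some genes that the rule chose are not reported here, and the counts of genes include them. Tnfrsf11a, Csf1r, Pmp22 and the genes named in the closing observations outside this rule were chosen after their values were seen.

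The steps were tested on simulated data drawn from the real genes' means and library sizes. Each gene took the trend of a group's spread at its level, not its own spread. The 200 changed genes per draw were far fewer than the 3594 real calls, so the adjusted threshold was stricter in the simulation. Over 10 draws of the comparison with the spread of each group as measured (12837 to 12876 genes tested, 200 changed genes in each), the test recovered 2.2% of 2-fold, 36.2% of 4-fold, 84.2% of 16-fold and 94.4% of 64-fold changes, and 4.15% of its calls were false. With the organoid spread in both groups (12343 to 12429 genes) it recovered 0.4%, 22%, 78.4% and 86.7%, and 7.54% of calls were false, with 3.77% to 13.2% in single draws, above the nominal level. With no changed genes 0 and 5 genes were called over the 10 draws, and 7.28% and 4.23% of genes had an unadjusted p under 0.05. Simulated genes are independent of each other. With none shifted camera called 0 lists, and it called 20 of 20 lists shifted 4-fold. Over the 10 draws with shifted lists it also called 5 and 4 other lists. The tendon and fibrocartilage list shares Fmod, Cilp and Cilp2 with the shifted cartilage matrix list, so these calls need not all be false. Because simulated genes are independent, the draws cannot show whether camera's p-values at the preset correlation hold for lists whose members vary together. In the real data the estimated correlation of the 9 called lists ran from -0.0412 (osteoblast markers) to 0.555 (cartilage matrix). With the estimated correlations 3 lists were called.

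Alternatives planned before the data were examined were RLE and upper quartile factors, total library size, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, a block for the replicate number, removal of the 100 most abundant genes, a test against a 2-fold change, and leaving out each library. A limma-voom fit with a weight per group was added after seeing the data. Figures were drawn with matplotlib.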

Results

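Gene expression was measured by mRNA sequencing in rat mandibular condylar chondrocytes, the cartilage cells of the jaw joint, grown either as a flat culture (2D culture) or as a condylar cartilage organoid, a small cartilage tissue grown in culture. Each group had 3 libraries. The 2D cells were kept in DMEM with 20% fetal bovine serum and the organoids in a chondrogenic medium, so culture format, medium and serum differed together and cannot be separated here. Total estimated counts were 26472447, 25856486 and 26248798 in 2D culture 1, 2 and 3, and 25656808, 18592574 and 24106567 in organoid 1, 2 and 3. Nothing in the labels says whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Levels are CPM after TMM scaling, as mean ± SD (n = 3), and log2 fold changes are organoid over 2D culture ± SE. Called genes have an adjusted p under 0.05 in edgeR's quasi-likelihood test. Runx2, Col1a1, Mki67 and Arid5b had a fractional count, a sign of shared reads, in 1 library each.

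The comparison asks how the organoid differs from the flat culture. Organoid libraries carried far more transcripts of cartilage matrix, hypertrophic cartilage and bone matrix genes and of genes of the hypoxia and glycolysis list, and fewer transcripts of contractile and cell cycle genes. Of 13052 genes tested, 3594 were called, 1944 higher and 1650 lower in organoids, and 3225 of them had a fitted change of at least 2-fold. At an unadjusted p under 0.05 there were 5304 genes, and 6986 genes (53.5%) had no overlap between the groups, against 10% by chance. The count fell when any 2D culture was left out, to 1114, 1211 and 1109 without 2D culture 1, 2 and 3. It rose when any organoid was left out, to 4589, 5321 and 4783 without organoid 1, 2 and 3. The test fits 1 spread per gene over both groups, whose spreads differ as given below. With total library size in place of TMM, 1063 genes were higher and 3529 lower (23.1% of calls higher, against 54.1%), after a shift of -0.611 in the median log2 fold change. Every called gene shared with any of these settings kept its direction, which genes called in 2 fits to overlapping data can hardly fail to do. Total library size kept 2713 of the 3594 calls.

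**Figure D1:**
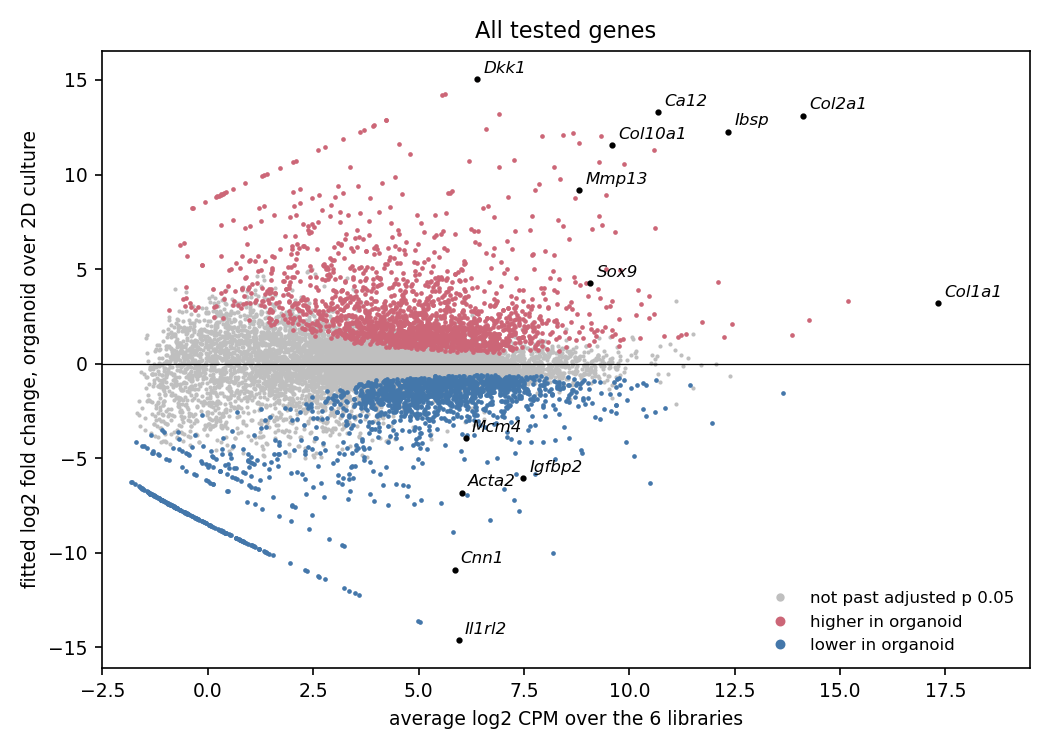
Fitted log2 fold change (organoid over 2D culture) against average log2 CPM for the 13052 tested genes; each point is a gene, red points are the 1944 called higher in organoids, blue points the 1650 called lower and grey points the rest. The diagonal lines of points at the edges are genes at 0 or few counts in a group, whose fitted fold depends on the prior count.

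Libraries of 2D culture resembled each other more than organoid libraries did. Spearman correlations of log2 CPM were 0.992 to 0.994 within 2D culture, 0.847 to 0.913 within organoids and 0.694 to 0.782 between the groups. The first principal component held 64.2% of the variance and the second 22.2%. Over 10569 genes, the median SD of log2 CPM was 0.115 in 2D culture and 0.614 in organoids, a ratio of 5.35. In organoids, 124 genes had at most 5 counts in a library and at least 100 in both others, against 0 genes in 2D culture.

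**Figure D2:**
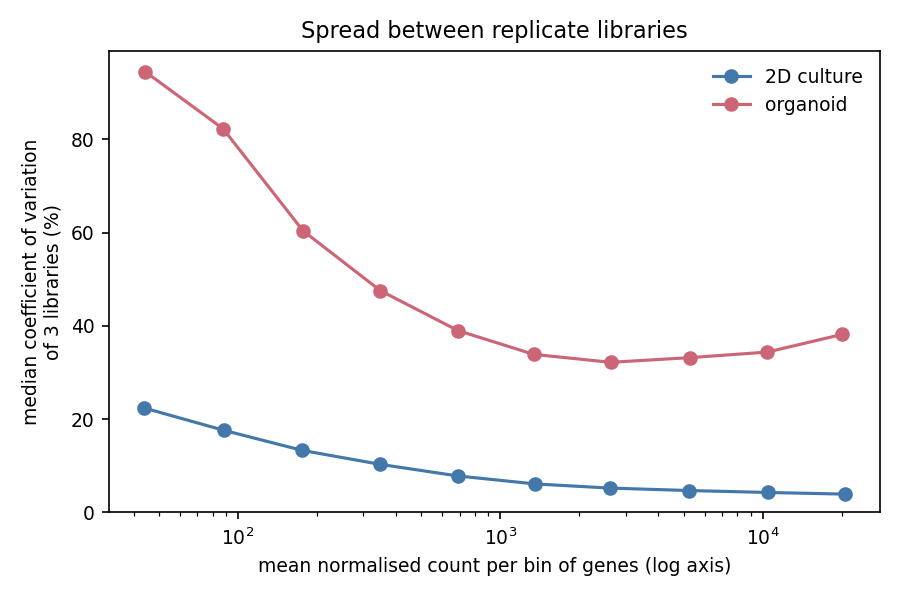
Median coefficient of variation of 3 libraries (percent) in 10 bins of genes by mean normalised count (log axis), for 2D culture (blue) and organoids (red). In the highest bin the value was 3.93% in 2D culture and 38.2% in organoids, and in the lowest bin 22.4% and 94.5%.

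Structural genes of hyaline cartilage rose together in organoids. Of 22 tested members of the cartilage matrix list, 17 rose, 0 fell and 5 did not pass (18 higher when adjusted over the list alone). Col2a1 (gene ID 25412), the main fibrillar collagen of cartilage, went from 4.01 ± 1.01 to 35560 ± 37838 CPM (log2 fold change 13.11 ± 1.33, edgeR adjusted p = 0.00133). The minor cartilage collagens Col9a1 and Col11a2 rose by 12.22 ± 1.78 and 12.01 ± 0.68, and Comp, a matrix protein that binds collagen, by 6.58 ± 1.04. Col9a1 lost its call with limma-voom (adjusted p = 0.112). Acan, the large aggregating proteoglycan, stood at 1460 ± 50.2 and 4346 ± 3469 CPM and did not pass (1.57 ± 0.57, adjusted p = 0.0824), although it passed without organoid 2 (adjusted p = 0.0164) and with DESeq2 (adjusted p = 0.0152), and also with limma-voom with a weight per group. Prg4, the lubricin gene of the joint surface, had 0.379 ± 0.238 and 2.39 ± 2.94 CPM and did not pass (adjusted p = 0.183). It shares reads with other genes in 5 libraries and passed without organoid 3 (adjusted p = 0.044). The organoids differed from each other in this group: Col2a1 was at 78321 CPM in organoid 1, 6414 in organoid 2 and 21945 in organoid 3. The list had a camera adjusted p of 8.73e-10, and an adjusted p = 0.393 with an estimated correlation, and 10, 9 and 9 members rose without 2D culture 1, 2 and 3.

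Most tested genes of the chondrogenic transcription factor list, which also holds the growth factor Gdf5, were higher. Of 15 tested, 11 rose, 1 fell and 3 did not pass (11 higher and 2 lower when adjusted over the list alone). Sox9 (gene ID 140586), the master regulator of cartilage, rose from 53.7 ± 2.09 to 1026 ± 360 CPM (4.26 ± 0.33, edgeR adjusted p = 0.000601). Foxa2, active in hypertrophic chondrocytes, had 0 counts in 2D culture and was at least 269-fold higher, and Erg, an articular cartilage factor, rose by 6.09 ± 0.48. Foxa3 was 600-fold higher (95% exact interval 205 to 2914, counting error only). Arid5b fell by 0.79 on the log2 scale and lost its call without each of 2D culture 1, 2 and 3. The list had a camera adjusted p of 0.000126, and an adjusted p = 0.257 with an estimated correlation, and 7 members rose without any of 2D culture 1, 2 and 3.

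**Figure D3:**
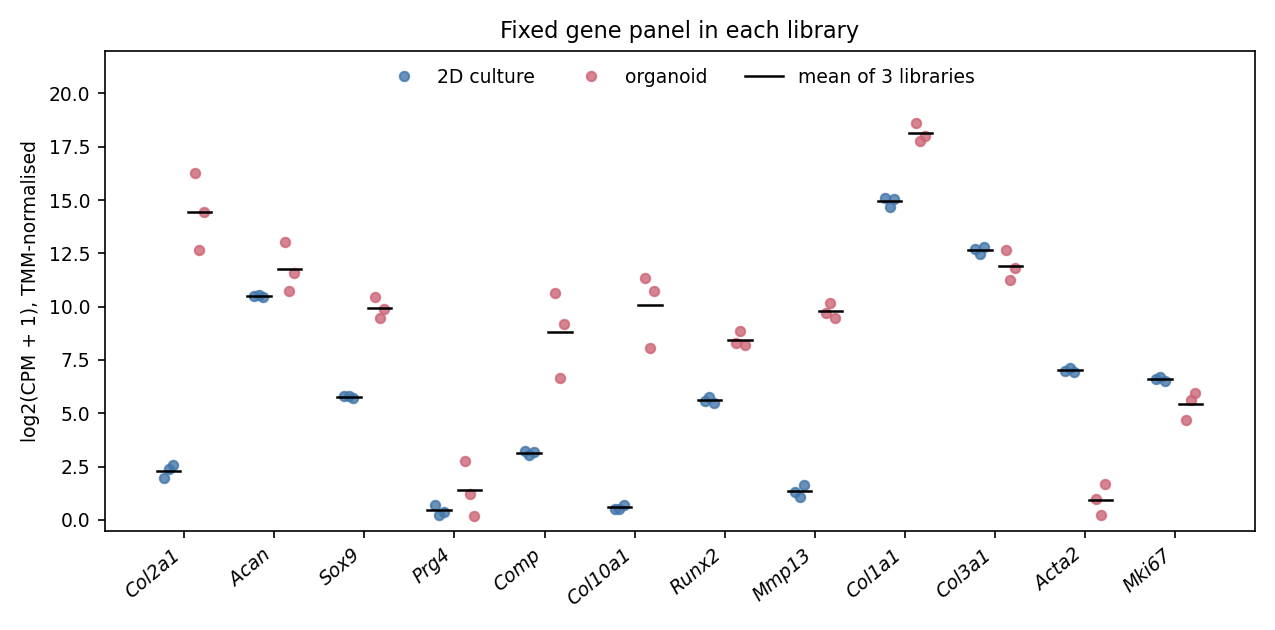
Level of the 12 panel genes as log2(CPM + 1) in each library, 2D culture in blue and organoids in red, with a line at the mean of 3 libraries. Col2a1, Sox9, Comp, Col10a1, Runx2, Mmp13 and Col1a1 were called higher, Acta2 was called lower, and Acan, Prg4, Col3a1 and Mki67 did not pass.

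Genes of hypertrophic cartilage and mineralised matrix rose with the cartilage genes. In the hypertrophy and mineralisation list 20 of 23 members rose, 0 fell and 3 did not pass (20 higher when adjusted over the list alone). Col10a1 (gene ID 25681), the collagen of hypertrophic chondrocytes, rose from 0.502 ± 0.128 to 1543 ± 1197 CPM (11.57 ± 1.13, edgeR adjusted p = 0.00117). Ibsp, a sialoprotein of mineralising matrix, rose from 2.10 ± 0.157 to 10355 ± 3611 CPM (12.27 ± 0.50). Mmp13, the collagenase of hypertrophic cartilage, rose by 9.16 ± 0.45 and Runx2, a regulator of hypertrophy and bone formation, by 2.89 ± 0.26. Ihh, a signal of prehypertrophic chondrocytes, was 4616-fold higher over 1 count in 2D culture (95% exact interval 828 to 182390, counting error only). The camera adjusted p was 1.16e-14, and with an estimated correlation the adjusted p = 0.0279.

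Osteoblast markers rose in organoids. Of 14 osteoblast markers, 9 of which the hypertrophy list also holds, 12 rose and 2 did not pass (13 higher when adjusted over the list alone; camera adjusted p 2.64e-10, adjusted p = 0.034 with an estimated correlation). Dmp1 and Mepe, matrix proteins of osteocytes, rose by 12.03 ± 0.74 and 10.72 ± 0.47, to 491 ± 67.7 and 146 ± 32.7 CPM. Of 7 osteoclast markers in the files, only 4 were tested, and the others, at 0.157 CPM or less in organoids, were removed by the low-count filter. Of the 4 tested osteoclast markers, 3 rose and 1 did not pass (3 higher when adjusted over the list alone). Nfatc1 rose by 3.23 ± 0.33, Acp5 by 3.50 ± 0.76 and Itgb3 by 2.08 ± 0.55. Acp5 and Itgb3 lost their calls without each of 2D culture 1, 2 and 3, leaving 1 called member. The list had a camera adjusted p of 0.0624, and Tnfrsf11a, the receptor that drives osteoclast formation, had 0 counts in organoids.

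Contractile genes fell. Of 25 tested contractile and mechanosensitive genes, 20 fell, 0 rose and 5 did not pass (23 lower when adjusted over the list alone). Acta2 (gene ID 81633), smooth muscle actin, fell from 128 ± 7.44 to 1.10 ± 1.01 CPM (-6.83 ± 0.75, edgeR adjusted p = 0.00179). Actg2 fell by 10.02 on the log2 scale, from 580 ± 18.2 to 0.573 ± 0.59 CPM. Cnn1, a calponin of smooth muscle, had 3 counts in organoids and was 2105-fold lower there (95% exact interval 720 to 10208, counting error only). The camera adjusted p was 2e-10, and with an estimated correlation the adjusted p = 0.0479.

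The fibroblastic matrix list moved both ways, with 8 members higher, 8 lower and 8 not past the threshold (8 higher and 9 lower when adjusted over the list alone). Col1a1 (gene ID 29393), the main collagen of bone and fibrous tissue, rose from 31906 ± 5027 to 295080 ± 92071 CPM (3.21 ± 0.36), and the small proteoglycan Dcn rose by 3.88 ± 0.20. The microfibril gene Fbn1 fell by 4.72 and Fbln2 by 4.06 on the log2 scale. Col3a1 did not pass (-0.65 ± 0.39, adjusted p = 0.252), although it passed without organoid 1 (-1.08, adjusted p = 0.0322) and with total library size (-1.34, adjusted p = 0.012). Its camera adjusted p was 0.937, and the median and mean were negative while the test pointed up. Without 2D culture 1 and without 2D culture 3, 5 members rose and 5 fell. Among 12 tendon and fibrocartilage markers, 2 fell and 10 did not pass (2 adjusted over the list alone, camera adjusted p 0.474, median 0.129 and mean -0.726). The tenocyte gene Tnmd fell by 6.36 on the log2 scale. Scx fell by 3.06 and lost its call without each of 2D culture 1, 2 and 3. Without organoid 1, 1 of these markers rose and 3 fell, and without organoid 2, 2 rose and 3 fell.

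Cell cycle genes were lower in organoids. Of 32, 24 fell, 0 rose and 8 did not pass (27 lower when adjusted over the list alone). Mcm4 and Mcm3, subunits of the replicative helicase, fell by 3.93 and 4.29 on the log2 scale, and Ttk, a mitotic checkpoint kinase, fell by 3.82. Mcm3 was at 7.66, 6.49 and 0.189 CPM in organoid 1, 2 and 3, so organoid 3 lay far below the other organoids. Mki67, a proliferation marker, had 96.3 ± 5.79 and 45.1 ± 18.8 CPM and did not pass (-1.10 ± 0.34, edgeR adjusted p = 0.0548), although it passed without organoid 1 (adjusted p = 0.0344), without organoid 3 (adjusted p = 0.0289), and with total library size, DESeq2, limma-voom and limma-voom with a weight per group (adjusted p = 0.0173 to 0.0317). The camera adjusted p was 1.64e-09, and with an estimated correlation the adjusted p = 0.257. Without 2D culture 1, 2 and 3 the number of members that fell was 10, 11 and 10, and Mcm3 was not among them. Of 19 cell cycle inhibitors and p53 targets, 3 rose and 5 fell (6 and 5 when adjusted over the list alone, camera adjusted p 0.937, median 0.0915 and mean -0.0915). Cdkn1c rose by 3.43 ± 0.50 and Gadd45a fell by 2.60 on the log2 scale. Leaving out a library gave 1 to 6 of these genes higher and 2 to 7 lower, and total library size 1 higher and 7 lower.

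Genes of low oxygen and glycolysis rose broadly. Of 34, 29 rose, 0 fell and 5 did not pass (30 higher when adjusted over the list alone). The carbonic anhydrase gene Ca12 rose from 0.318 ± 0.276 to 3296 ± 1986 CPM (13.32 ± 1.28), Ca9 rose by 7.25 ± 0.57 and Egln3, an oxygen-sensing prolyl hydroxylase, by 9.01 ± 0.58. The camera adjusted p was 2.88e-15, and with an estimated correlation the adjusted p = 0.257. In the oxidative phosphorylation list 10 of 36 members fell, 0 rose and 26 did not pass (13 lower when adjusted over the list alone). Ndufa4 fell by 1.59, Cyc1 by 1.19 and Cox5a, which shares reads with other genes in 5 libraries, by 1.27 on the log2 scale. The camera adjusted p was 0.000184, and with an estimated correlation the adjusted p = 0.393. That count was 3 without any of 2D culture 1, 2 and 3, 23 without organoid 2 and 26 with total library size.

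Enzymes that fold and crosslink collagen rose in part. Of 30, 15 rose, 2 fell and 13 did not pass (17 and 2 when adjusted over the list alone, camera adjusted p 6.14e-05, adjusted p = 0.486 with an estimated correlation). P3h2, a collagen prolyl hydroxylase, rose by 10.39 ± 1.08 and the crosslinking enzyme Loxl4 by 8.76 ± 0.58, while P4ha3 fell by 3.23 on the log2 scale. The number that rose was 6, 8 and 6 without 2D culture 1, 2 and 3, and 8 with total library size. Among 27 genes of glycosaminoglycan synthesis 10 rose and 3 fell (10 and 3 when adjusted over the list alone, camera adjusted p 0.0775), and 16 rose without organoid 2, while total library size gave 5 lower and a leave-out of 1 library 0 to 4 lower. Xylt1, which starts the chains on proteoglycans, rose by 4.39 ± 0.41 and the sulfotransferase Chst11 by 3.61 ± 0.34. Among 26 matrix proteases and inhibitors 4 rose and 4 fell (4 and 5 when adjusted over the list alone, camera adjusted p 0.382), and 2 fell without any of 2D culture 1, 2 and 3 against 9 without organoid 1 and 10 with total library size. The urokinase gene Plau fell by 5.92 on the log2 scale and lost its call without each of 2D culture 1, 2 and 3.

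Signalling genes moved in both directions. Of 32 TGF-beta and BMP genes 11 rose and 6 fell (11 and 6 when adjusted over the list alone, camera adjusted p 0.728, median -0.0516 and mean 0.0586). Of 29 Wnt genes 12 rose and 5 fell (13 and 8 when adjusted over the list alone, camera adjusted p 0.172). The Wnt inhibitor Dkk1 had 0 counts in 2D culture and was at least 5530.4-fold higher, and Frzb, another inhibitor, rose by 12.07 ± 1.59 and lost its call with limma-voom (adjusted p = 0.0544). Of 30 hedgehog, FGF and IGF genes 8 rose and 4 fell (9 and 4 when adjusted over the list alone, camera adjusted p 0.246). The hedgehog targets Gli1 and Hhip were higher, Gli1 by 6.11 ± 0.91 and Hhip, at 0 counts in 2D culture, at least 1039-fold, while Igfbp2 fell by 6.06 on the log2 scale. Total library size turned the TGF-beta and BMP counts to 5 higher and 12 lower and moved the Wnt genes to 8 lower. Without any of 2D culture 1, 2 and 3 at most 5 TGF-beta and BMP genes and at most 7 Wnt genes rose and at most 2 Wnt genes fell, and 8 Wnt genes fell without organoid 1. Without organoid 2, 10 TGF-beta and BMP genes fell and 13 hedgehog, FGF and IGF genes rose.

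Genes of inflammation fell more often than they rose, with 1 of 15 higher and 5 lower (1 and 6 when adjusted over the list alone, camera adjusted p 0.15). The chemokine gene Ccl2 had 1 count in organoids and was 1017-fold lower (95% exact interval 182 to 40171, counting error only). Of 16 interferon response genes 1 rose and 2 fell (1 and 2 when adjusted over the list alone, camera adjusted p 0.15). Of 15 glucocorticoid response genes 7 rose and 2 fell (8 and 2 when adjusted over the list alone, camera adjusted p 0.0676). Ddit4 rose by 4.13 ± 0.25 and Glul fell by 2.30 on the log2 scale. Of 22 serum and immediate early genes 7 rose and 4 fell (8 and 4 when adjusted over the list alone, camera adjusted p 0.728), with Hbegf lower by -5.25 ± 0.72. Of 27 genes of the unfolded protein and integrated stress response 2 rose and 4 fell (2 and 4 when adjusted over the list alone, camera adjusted p 0.382). Of 26 lysosome and autophagy genes 3 rose and 1 fell (2 and 0 when adjusted over the list alone, camera adjusted p 0.937, median -0.222 and mean 0.197), and Ulk1 rose by 3.40 ± 0.37. Of 21 lipid genes 1 rose and 4 fell (1 and 4 when adjusted over the list alone, camera adjusted p 0.598). Of 23 cholesterol synthesis genes 3 rose (0 when adjusted over the list alone, camera adjusted p 0.937, median -0.0869 and mean 0.0191). Total library size turned that list to 0 higher and 4 lower, and the serum response list to 4 higher and 8 lower, and moved the lysosome list to 1 higher and 13 lower, the stress response list to 1 higher and 13 lower, and the lower counts of the lipid and interferon lists to 7 and 5. Without any of 2D culture 1, 2 and 3 there were 3 glucocorticoid genes higher, at most 2 serum response genes higher and 0 cholesterol genes higher, 3 inflammation genes and 1 interferon gene lower, at most 1 lipid gene lower, 1 lysosome gene higher and 0 lower, 0 inflammation and 0 interferon genes higher, and at most 1 stress response gene higher and 0 lower. Without organoid 1, 7 interferon, 8 stress response, 7 lysosome and 7 serum response genes were lower. Without organoid 2, 4 lipid, 8 lysosome and 5 cholesterol genes were higher. Over all leave-outs of 1 library, 0 to 4 stress response genes were higher and 0 to 8 lower. The ranges were 1 to 9 higher and 2 to 7 lower for serum response genes, and 0 to 5 higher and 0 to 2 lower for cholesterol genes. Of all tested genes 27.5% were called with the 6 libraries. The interferon, stress response, lysosome, lipid and cholesterol lists held a smaller share of calls than that.

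**Figure D4:**
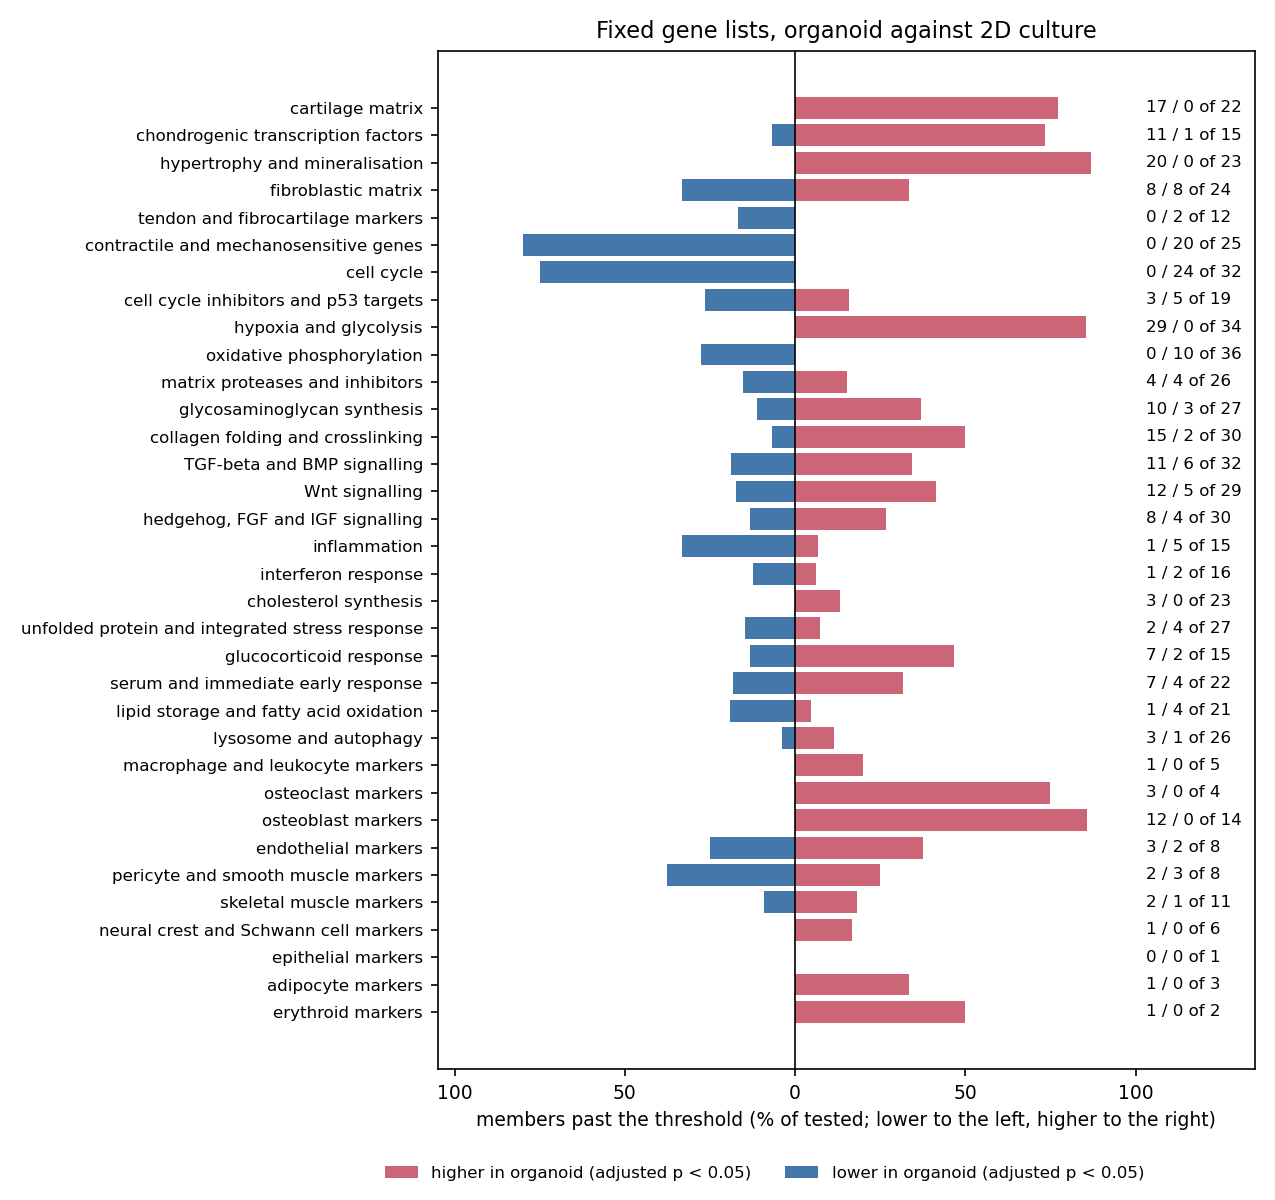
Members of each fixed list past the threshold, as a percent of the tested members, with those higher in organoids to the right in red and those lower to the left in blue; the numbers give higher, lower and tested members. The cartilage matrix, hypertrophy and hypoxia lists have 17, 20 and 29 members higher and 0 lower, and the contractile and cell cycle lists have 20 and 24 lower and 0 higher.

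Most markers of cell types other than osteoblasts and osteoclasts were low in organoids, with exceptions such as Cspg4 and Pmp22. The median levels there were 0.5715 CPM for endothelial, 0.15 for macrophage and leukocyte, 0.563 for skeletal muscle, 0.254 for Schwann cell, 0.292 for adipocyte, 0.336 for erythroid, 0.0951 for epithelial and 1.845 for pericyte and smooth muscle markers. Among 8 endothelial markers 3 rose and 2 fell (4 and 2 when adjusted over the list alone, camera adjusted p 0.305). Plvap was 741-fold higher (95% exact interval 253 to 3600, counting error only), Esam rose by 5.97 ± 0.83, and Cldn5, at 0 counts in 2D culture, was at least 86.2-fold higher but lost its call without each of 2D culture 1, 2 and 3. Eng fell by 1.47 on the log2 scale and lost its call without 2D culture 1 and without 2D culture 3. Without organoid 1, 4 endothelial markers rose and 4 fell, and without organoid 2, 4 pericyte and smooth muscle markers rose and 4 fell. Of 8 pericyte and smooth muscle markers 2 rose and 3 fell (3 and 4 when adjusted over the list alone, camera adjusted p 0.762), with Myh11 lower by -5.06 ± 0.76. Cspg4, which pericytes express, rose from 194 to 749 CPM (1.95 ± 0.44) and lost its call without each of 2D culture 1, 2 and 3, which left 0 markers of this list higher, and the Schwann cell marker Pmp22 was at 116 CPM in 2D culture and 254 in organoids and did not pass. The remaining lists had 1 of 5 macrophage, 2 of 11 skeletal muscle, 1 of 6 Schwann cell, 1 of 3 adipocyte, 1 of 2 erythroid and 0 of 1 epithelial markers higher, and 1 skeletal muscle marker lower, with the same numbers when adjusted over the list alone. Without organoid 2, 5 skeletal muscle markers were higher, 2 Schwann cell markers higher and 2 lower, and 1 epithelial marker higher. Without organoid 1, 3 skeletal muscle, 1 Schwann cell and 1 adipocyte markers were lower and 2 erythroid markers higher, and without organoid 3, 3 macrophage markers were higher. Their camera adjusted p was 0.328 for macrophage, 0.728 for skeletal muscle and 0.937 for Schwann cell and adipocyte markers, and the erythroid and epithelial lists were too short to test. Csf1r, a macrophage growth factor receptor, was removed by the low-count filter, with 16.4 CPM in organoids (0.142 to 32.5) and 0.144 CPM in 2D culture. S100b, which chondrocytes also express, rose by 3.05 ± 0.37, and Fabp4 by 4.60 ± 0.66. The calls for the macrophage gene Lyz2, the muscle genes Tnni2, Tnnt3 and Myh3 and the globin Hba-a1 ended without each of 2D culture 1, 2 and 3. Lyz2, Myh3 and Hba-a1 share reads with other genes in 2, 2 and 3 libraries, so their values are uncertain.

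The genes of largest change lay outside the lists in part. Besides Dkk1, the genes Clec3a, Steap4, Kcna5 and Slco2b1 had 0 counts in 2D culture and were at least 3192-, 2922-, 1215- and 979-fold higher in organoids. Clec3a, a cartilage lectin, lost its call without each of 2D culture 1, 2 and 3. Tmem255b was 11478-fold higher over 2 counts (95% exact interval 3177 to 94784, counting error only). In the other direction, Il1rl2, Scrn1, Pappa2, Plekha7, Ano5, Nkain4, Dner and Edn1 had 0 counts in all 3 organoid libraries. Il1rl2, a receptor of the interleukin-1 family, was at least 2253-fold lower and Edn1, the endothelin-1 gene, at least 247-fold lower. Over all calls, 201 genes were at 0 counts in the lower group and 106 at 1 to 3 counts.

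A few genes took much of the organoid libraries. The 10 most abundant genes held 39.3% ± 3.47 of counts in organoids and 12.2% ± 0.557 in 2D culture, and Col1a1 alone held 23.1% ± 3.18 and 3.96% ± 0.569. The 100 most abundant genes held 52.0% ± 5.25 and 27.6% ± 0.539. The cartilage matrix list held 4.51% ± 3.33 and 0.611% ± 0.0166, at 8.19%, 1.72% and 3.61% in organoid 1, 2 and 3. Ribosomal protein genes held 1.59% ± 0.565 and 2.74% ± 0.241. For each of the 5 shares the groups did not overlap, and the two-sided exact permutation p was 0.1 (0.1 after adjustment), the smallest that 3 against 3 libraries allow.

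Of the 32 lists tested with camera, 9 were called, 6 higher and 3 lower. With an estimated correlation 3 were called: hypertrophy and mineralisation, osteoblast markers, and contractile and mechanosensitive genes. Other groupings of the same libraries into 3 and 3, which mix organoids with 2D cultures, gave up to 13 called lists.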

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

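The fit with a weight per group was chosen after seeing the data, and the other alternatives before. Of 3594 called genes, no call shared with any alternative changed direction, and no named gene changed direction. A gene called in 2 fits to the same counts can hardly differ in direction, so the shared calls say little on robustness. Of the 3594 calls, 2713 were kept with total library size and 2573 with the replicate block. Over RLE and upper quartile factors, DESeq2, limma-voom, both other filters and removal of the 100 most abundant genes the number of calls was 3293 to 5247, and with a weight per group 3769. Limma-voom turned the balance to 1942 higher and 2478 lower (43.9% higher), against 1944 and 1650 (54.1%). Total library size gave 4592, with 1063 higher and 3529 lower. Leaving out a library gave 1109 to 5321 calls, 1109 to 4240 over 2-fold, 70 to 110 named genes past the threshold in place of 111, and 9 to 11 lists. The lower ends come from leaving out a 2D culture: 1114, 1211 and 1109 calls without 2D culture 1, 2 and 3, all of them also called with the 6 libraries. The test fits 1 spread per gene over both groups, although organoids were far more spread out. Whether this is the cause was not tested. A test against a 2-fold change called 1494 genes in place of 3225 (888 higher, 606 lower), by its stricter null. Camera called 9 lists, 3 with an estimated correlation, and fry 17. Whether replicate numbers pair the libraries could not be decided with 3 libraries per group. Correlations of same-numbered deviations were 0.0606, 0.187 and 0.0207. These were the highest for 2D culture 1 and 2, while 2D culture 3 correlated best with organoid 1 (0.0698). With a replicate block 2730 genes were called (1441 higher, 1289 lower), 2686 over 2-fold, 99 named genes and 10 lists. Besides the calls that ended without a 2D culture, those of Clec3a (limma-voom), Itgb3 and Tnnt3 (total library size), Lyz2 (without organoid 1), Arid5b and Myh3 (a weight per group), Tnnt3 (no filter) and Arid5b, Myh3, Hba-a1, Tnni2 and Tnnt3 (the replicate block) ended. Depth limits genes at 0 counts, where 3 counts are 0.0917 to 0.18 CPM in a library. The wide spread among organoids limits small changes: at the measured spread simulated 2-fold changes were recovered in 2.2% of cases. Each draw had 200 changed genes. The real data held more called genes and so a less strict adjusted threshold, and this share may not hold for them.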

Other observations

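The gene families in the first paragraph below were chosen after seeing the data, and so were the tests of shared deviations, of genes above 2000 counts (both of them), of endothelial cells and of separate cartilage and bone parts. The splits of the libraries, the thinning and the slope over all genes were planned before their results were seen.

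Basement membrane collagens and most tubulins, outside the fixed lists, were lower in organoids. All 4 tested basement membrane collagens fell, among them Col4a1 (-3.97 ± 0.53) and Col4a2 (-3.07 ± 0.44). Of 10 tubulins 8 fell, with Tubb6 at -1.85 ± 0.20. Of 14 cytosolic aminoacyl-tRNA synthetases 7 fell, with Wars1 at -1.68 ± 0.28. Of 88 cytosolic ribosomal protein genes 11 fell and 77 did not pass, a share near that of all tested genes, of which 1650 of 13052 fell. Many of these ribosomal genes share reads with others. The camera adjusted p over 8 families was 0.00252, 0.000556, 0.00594 and 0.013 in that order, and with an estimated correlation the adjusted p = 0.39, 0.426, 0.39 and 0.715. Vacuolar ATPase subunits had 3 of 19 lower and laminins 2 of 9 lower, with camera adjusted p 0.0862 each. Integrins had 3 of 19 higher and 4 lower (camera adjusted p 0.94). The collagen receptor subunit Itga10 rose by 5.40 ± 0.30 and Itgb1, the common beta chain, fell by 1.63 on the log2 scale. Of 9 cadherins 1 rose, Cdh2 by 2.52 ± 0.24, and 3 fell, with Cdh11 at -1.85 ± 0.24 (camera adjusted p 0.0953). The ribosomal family lost its camera call without organoid 1 (adjusted p 0.405) and without organoid 3 (adjusted p 0.0555). Total library size raised the lower counts to 27 ribosomal genes, 11 synthetases and 11 vacuolar ATPase subunits (camera adjusted p 0.04 for the last). It turned the integrin median from 0.168 to -0.423, and that median was also below 0 without organoid 1 (-0.403). Without any of 2D culture 1, 2 and 3 the numbers that fell were 2 basement membrane collagens, 2 tubulins, 1 synthetase and at most 1 ribosomal gene, with 0 integrins, laminins and vacuolar ATPase subunits lower and 1 integrin higher. Without organoid 2, 48 ribosomal genes fell. Leaving out a library gave 0 to 6 vacuolar ATPase subunits lower.

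The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 3594 genes and the other splits at most 0, it called 3225 genes over 2-fold against at most 0, and for each of these 1 split, the real one, gave a count as large. For the lists the real split called 9 and the highest other split 13, and 8 of the 10 splits called at least 9. The other splits mix organoids with 2D cultures, so the difference between the groups lies partly between and partly within their sides. It widens the spread within a side and lowers the gene calls, so the 0 calls say nothing on chance.

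Organoid libraries were 5.35 times as spread out as 2D libraries in the median SD of log2 CPM, and the depth left after the abundant genes is argued against as the whole cause: after every library was thinned to 10044661 counts outside the 100 most abundant genes the ratio stayed at 4.97, over 9827 genes. RNA from few molecules, whose squared CV falls with the mean, is argued against as the whole cause for genes above 2000 counts: the excess rose there (0.16, 0.166, 0.194 and 0.257), with a log2 slope of 0.232 (0.123 to 0.337 over resampled genes, 0.0702 to 0.291 in pairs of organoids), and was 8.54 to 105 times the value scaled from the lowest bin, although the lowest ratio is short of its bound of 10. It stays open for the other genes, since the slope over all bins was -0.273 (-0.352 to -0.217 without a bin, and -0.476 in 2D culture), between the bounds of -0.5 and -0.25. The slope test above 2000 counts was added after the ratio had missed its bound and the rise over these bins had been seen. Its range over resampled genes treats genes as independent and does not cover the spread between organoids. A difference between organoids in whole gene groups may account for part: deviations of the 22 cartilage genes followed a common profile for 51.1% of their sum of squares, at percentile 100 of 10000 random lists matched on expression (median 5.82%), with means of 1.37, -1.34 and -0.03 in organoid 1, 2 and 3. Of the 6 sets looked at, with no adjustment for their number, the others reached percentiles of 98.8 (cell cycle), 95.2 (hypoxia and glycolysis), 82.5 (oxidative phosphorylation), 58.4 (subunits MCM2 to MCM7) and 36.5 (osteoblast markers), and whether separate animals or cultures lie behind the libraries was not tested. Single MCM subunits were very low in different libraries. Mcm3 was at 0.189 CPM in organoid 3. Mcm5 and Mcm6 were at 0.541 and 0.481 CPM in organoid 2, against 8.43 and 20.7 in organoid 1 and 18.4 and 23.8 in organoid 3. The size of the falls of these subunits is therefore uncertain.

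Plvap, Esam and Cldn5 rose in organoids, and endothelial cells could be their source. Those cells bring all their abundant transcripts, but the 13 other endothelial markers had a median ratio to Plvap of at most 0.0363 in any organoid library (0.0363, 0 and 0), under the bound of 0.1. Plvap was at 22.7, 35.9 and 12.4 CPM in organoid 1, 2 and 3, and Kdr at 0 in all 3. The median hides Eng at 27.2, 23.6 and 16.3 CPM and Egfl7 at 12.5, 4.63 and 5.87 CPM in organoid 1, 2 and 3. Both were higher in 2D culture, with means of 61.8 and 21.1 CPM. Pecam1, Cdh5, Tie1, Vwf and Emcn were at 0.471, 0.825, 1.12, 1.12 and 0.295 CPM in organoid 1, and Sox18 at 4.99 and 3.03 CPM in organoid 2 and 3 (at most 0.371 in 2D culture), so a small number of such cells is not excluded. Expression of these genes by other cells of the organoid stays open and was not tested.

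Cartilage and bone genes were high in the same organoids. A candidate explanation is that the organoids have parts, some with cartilage and some with bone gene expression, in changing proportion. The list means then move against each other, and they did so in 3 of 3 pairs of libraries. Libraries in random order do this in 16.7% of cases, and the osteoblast means (-0.11, 0.15 and -0.05) ranged over 0.26 with an SE of up to 0.157, against 2.71 for cartilage, so the support is weak. The osteoblast markers also showed no clear common profile (5.61% shared, against a median of 8.23% in random lists). Members went both ways: Col1a1 and Ibsp were highest in organoid 1, as Col2a1 was, while Dmp1 and Mepe were lowest there. Cells that express both groups of genes are not excluded by bulk counts.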
